A study of Mus musculus with 4 samples.

How the data were processed

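RNA was profiled on 4 Affymetrix arrays, each from Flk-1-positive cells that had been sorted from mouse embryonic stem (ES) cells after 3 days of differentiation. Flk-1 (gene Kdr) is the VEGF receptor that marks the mesoderm from which blood and vessels form. ER71 is the ETS-family transcription factor encoded by Etv2. There was 1 array for each of 4 groups: an inducible ER71 line (iER71) with doxycycline, the same line without it, Er71-deficient cells and wild-type cells. Per the labels, the treated culture received doxycycline at 1 mg/ml from day 2 to day 3, and the RNA was amplified from small inputs before labelling.

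The labels of the iER71 arrays disagree. The array whose source and characteristics say that no doxycycline was given carries a title calling it ER71 overexpressed, and the array that received doxycycline carries a title calling it control. Groups follow the titles, and no array was reassigned. Where only 1 label is given below, the array with doxycycline is the one titled control and the array without it is the one titled ER71 overexpressed; the direction opposite to the titles was computed as an alternative.

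The values were analysed as deposited: a linear intensity for each of 23332 probe sets on each array, already summarised and normalized by the authors. The submitters' processing notes name Affymetrix Expression Console, RMA and the genome build mm8, with no version or order. RMA usually returns log2 values, whereas the deposited intensity values are linear, so log2 was taken of them. Median intensities were 71.3 without doxycycline, 72.3 with doxycycline, 71.3 for Er71-deficient cells and 71.7 for wild type. Many deposited intensity values were exactly equal on 2 arrays: 9230 probe sets (39.6%) had such a tie, between 15.1% and 20.0% of probe sets for any pair of arrays. A difference of exactly 0 between arrays is therefore common in these values, and it shrinks list medians towards 0. No detection call came with the values, so the level of the background is unknown. No probe coordinates were used, because the gene table at hand is of another build.

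Gene names came from the platform's annotation. It gave exactly 1 symbol for 14996 probe sets, several for 1019 and none for 7317; 14941 of the first kind had a gene number in the reference gene table, and no symbol changed through it. Genes were named only from probe sets with 1 symbol. Of a gene's several probe sets (135 genes), the brightest on average over the arrays was used, which left 14860 genes. A gene counted as detected if its brightest array reached the median of all values (intensity 71.6, log2 6.16), and 8843 genes did.

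With 1 array per group there is no spread between replicates, so no test, error or p-value is given for any gene. The design had assumed log2 values; its comparison was kept, with the log2 taken here. Genes were called by size alone, at a difference of at least 1 on the log2 scale (2-fold). The arrays with doxycycline (titled control) and of wild type were also compared, as a gauge of how far arrays of the reference populations lie apart. For 19 gene lists the median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins; the percentile describes these arrays only. The middle 95% of random lists lies between the 2.5th and 97.5th percentiles. Fold calls and list percentiles were tested on simulated data with 200 changed genes among 8843. Of genes changed by 1.5 on the log2 scale, 100% were called in the simulated iER71 and Er71-deficient pairs and 97% in the simulated control pair; 7%, 5% and 5% of 100 unshifted lists of 25 genes fell outside the middle 95%. The simulated noise was the robust spread of all genes with unequal values in the pair and not a replicate error. That noise was small against a change of 1.5 and the same for dim and bright genes. The high share of calls therefore follows largely from the setting and says little about real fold calls. Simulated genes varied independently and had no ties, so these shares say little about real lists, whose members may vary together. The number of arrays limits the precision of every value.

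The genes named were chosen by a rule fixed before the data were examined: Etv2 and Kdr; the 12 largest differences each way in the iER71 and Er71-deficient pairs and the 5 largest each way in the control pair, leaving out predicted gene models and olfactory and vomeronasal receptors (4, 5 and 7 such symbols passed 2-fold in the iER71, Er71-deficient and control pairs); up to 4 members of each list with the largest difference; and up to 15 genes past 2-fold in opposite directions in both pairs, with 5 in the same direction. Not every gene that the rule takes is reported here. The lists covered endothelium, blood, heart, primitive streak, the Wnt pathway, paraxial and lateral mesoderm, smooth muscle and pericytes, pluripotency, endoderm, neuroectoderm, fibroblast feeders, immediate-early and stress genes, hypoxia and glycolysis, proliferation, the Notch pathway, the BMP and TGF-beta pathways, VEGF, FGF and MAPK signalling, the ETS family, and ribosomal proteins. Alternatives fixed in advance were other detection filters, cyclic loess, median centring, a further quantile normalization, the mean of a gene's probe sets, an offset of 32 on the linear scale, sizes of 1.5-fold and 3-fold, and the turned sign. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 (cyclic loess and quantile normalization), were used.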

Results

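The data describe day 3 Flk-1-positive mesoderm in 4 states, with 1 array each: the iER71 line with and without doxycycline, Er71-deficient ES cells and wild-type ES cells. The design sets gain of ER71 against its control and loss of ER71 against wild type. No group had a replicate, so every value below is a single measurement, and sizes are given without error. On the log2 scale the arrays correlated across all probe sets with Pearson's r between 0.967 and 0.979.

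Etv2, the gene for ER71, was bright on every array. Its log2 intensity was 10.50 on the iER71 array with doxycycline (titled control) and 10.05 on the iER71 array without doxycycline (titled ER71 overexpressed), so it was 1.37-fold higher on the array titled control, against the titles. It was 9.39 on the wild-type array and 8.89 on the Er71-deficient array, 1.42-fold higher in wild type. Neither difference reached 2-fold. The probe positions relative to the deleted part and to the inducible gene are not given in the sources used here, so Etv2 is a weak check of the labels. Kdr, the marker used for sorting, differed little, with log2 intensities of 10.19 with doxycycline, 9.96 without, 9.89 in wild type and 9.67 in Er71-deficient cells.

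**Figure D1:**
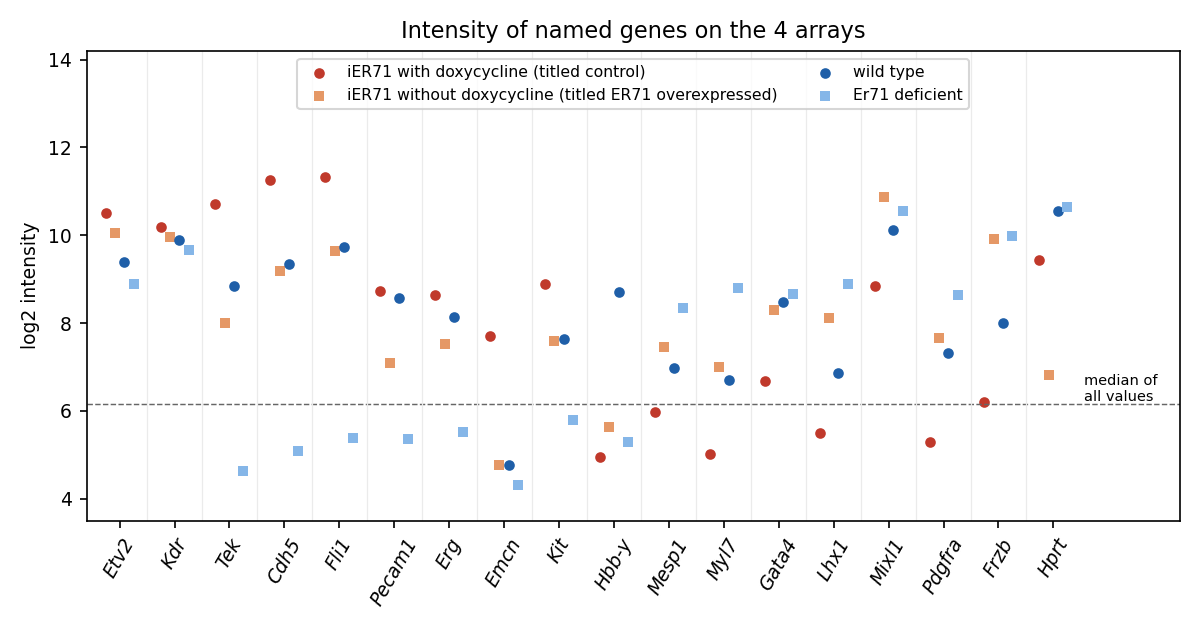
Log2 intensity (vertical axis) of 18 named genes on each of the 4 arrays, 1 point per array; the dashed line is the median of all values, 6.16. Tek, Cdh5 and Fli1 are brightest with doxycycline (titled control) and lie below the line in Er71-deficient cells, where Mesp1, Myl7, Lhx1 and Pdgfra are brightest.

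The first comparison asks how Flk-1-positive mesoderm of the inducible line differed with gain of ER71. Of 8843 detected genes, 213 were at least 2-fold higher on the doxycycline array (titled control) and 109 were at least 2-fold higher on the array without doxycycline (titled ER71 overexpressed); 27 genes each way reached 4-fold. The endothelial list held 20 of the 213, and the cardiac list 6 of the 109. Higher with doxycycline were Tmem255a (11.5-fold), the endothelial sialomucin Emcn (7.68-fold), the integrin Itga2 (6.96-fold), Myct1 (6.83-fold), the angiopoietin receptor Tek (6.61-fold), the vasoconstrictor peptide gene Edn1 (6.40-fold), Hprt of purine salvage (6.14-fold), the RNA sensor Tlr3 (6.08-fold), the potassium channel subunit Kcne3 (5.72-fold), the leukocyte actin-bundling gene Lcp1 (5.53-fold), the immune GTPase Gimap4 (5.30-fold) and the SNARE gene Vamp5 (5.22-fold). Higher without doxycycline were the secreted Wnt antagonist Frzb (12.9-fold), the G-protein regulator Rgs5 (12.5-fold, with 1.55 on the log2 scale from another probe set), Asb4 (11.1-fold), the ligand Bmp5 (10.4-fold), the imprinted gene Phlda2 (8.34-fold), the mesenchymal cadherin Cdh11 (7.28-fold), the LIM homeobox gene Lhx1 (6.21-fold), Pdlim3 (5.57-fold), the glypican Gpc3 (5.33-fold), the matrix proteoglycan Vcan (5.32-fold), the growth factor receptor Pdgfra (5.17-fold) and the BMP-binding gene Bmper (5.11-fold).

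Of 31 detected members of the endothelial list, which includes the sorted marker Kdr, 20 were at least 2-fold higher with doxycycline (titled control) and none lower by that size. The list's median difference was 1.23 on the log2 scale, above the random lists' middle range of -0.03 to 0.09. Besides Emcn and Tek, the largest were the vascular cadherin Cdh5 (4.19-fold) and the tight-junction gene Cldn5 (4.09-fold). In the ETS family, 5 of 14 detected members were at least 2-fold higher with doxycycline and 1 at least 2-fold lower, with a median of 0.40, above the random range: Fli1 (3.24-fold), Elk3 (3.13-fold) and Ets2 (2.42-fold) were higher, while Etv5 was 4.73-fold higher without it. In the blood list 3 of 22 members were at least 2-fold higher with doxycycline, and the median of 0.02 lay within the random range. Those were Fli1, which is also in the endothelial and ETS lists, the cytokine receptor gene Kit (2.44-fold) and Ikzf2 (2.06-fold); Runx1, a regulator of blood emergence, was 1.87-fold higher without doxycycline.

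Cardiac genes were higher without doxycycline (titled ER71 overexpressed): 6 of 16 passed 2-fold that way and 1, Mef2c (named after its value was seen), passed it with doxycycline, for a median of -0.68 (doxycycline minus untreated). Fgf10 (4.54-fold), the atrial myosin light chain Myl7 (3.98-fold), the transcription factor Gata4 (3.11-fold) and the early cardiac mesoderm factor Mesp1 (2.76-fold) were the largest. Of 15 primitive streak genes, 5 passed 2-fold in that direction and none in the other, with a median of -0.38; beside Lhx1 and Mesp1 they included Mixl1 (4.09-fold) and Eomes (3.04-fold). Of 35 Wnt pathway genes, 6 passed 2-fold in that direction and none in the other. They held ligand, receptor and agonist genes as well as the antagonist Frzb: Rspo3 was 4.34-fold, Wnt5a 4.19-fold and Fzd7 2.84-fold higher without doxycycline, and the list's median was only -0.11. In the BMP and TGF-beta list 4 of 24 passed 2-fold that way, with Tgfb2 (5.02-fold), Bmp4 (3.82-fold) and Msx2 (2.58-fold) after Bmp5, while the median was -0.01. In the paraxial and lateral mesoderm list 2 of 11 did, Pdgfra and Msgn1 (4.57-fold), with a median of -0.22. The smooth muscle and pericyte list had 1 of 9, the calponin gene Cnn1 (2.56-fold), and a median of -0.31. Of the lists in this paragraph, the medians lay below the random range apart from that of BMP and TGF-beta.

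Markers of other populations that the gate could hold differed less evenly in this pair. In the pluripotency list Dppa4 (4.32-fold) and Utf1 (3.02-fold) were higher with doxycycline, whereas Tdgf1 (4.93-fold) and Tbx3 (2.82-fold) were higher without it; the list's median was -0.04, within the random range, but -0.76 and below it with the stricter detection filter. Of 14 endoderm genes, 2 were at least 2-fold higher with doxycycline, among them Dab2 (2.63-fold), and 3 were at least 2-fold higher without it, namely Pdgfra, Cer1 (2.58-fold) and Spink1 (2.54-fold), for a median of -0.07. One neuroectoderm gene of 12, Fabp7 (2.16-fold), passed 2-fold, being higher without doxycycline, and the median was -0.01, within the random range. With the stricter filter only Fabp7 and Otx2 were left of this list, with a median of -0.99, below the range. The VEGF, FGF and MAPK list had Flt1 (2.61-fold) higher with doxycycline, Etv5 higher without it, and a median of -0.18, below the random range, but -0.0034 and within it with the stricter filter. Pdk1 (3.68-fold, with doxycycline) was the 1 gene past 2-fold among 12 of hypoxia and glycolysis, whose median was 0.01. No member passed 2-fold among 7 fibroblast feeder genes (median -0.04), 16 immediate-early and stress genes (0.04), 19 proliferation genes (0.03), 16 Notch pathway genes (-0.03) and 8 ribosomal protein genes (0.03); in these lists apart from proliferation the mean had the other sign. Mki67, a proliferation marker, was 1.14-fold higher with doxycycline, and Notch1 was 1.64-fold higher.

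The comparison rests on 1 array each, and which array carried more ER71 is not settled by the labels. Many of these genes lay below the detection level on the dimmer array (Emcn at log2 4.76 and Edn1 at 5.81 without doxycycline, Rgs5 at 5.69 and Bmp5 at 5.44 with it), where the size of a fold is uncertain. Ikzf2 was under 2-fold after median centring or quantile normalization, and Erg, Lgr5, Msx2 and Ikzf2 were with an offset on the linear scale.

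The second comparison asks how Flk-1-positive mesoderm differed with loss of ER71. On the Er71-deficient array 140 genes were at least 2-fold lower than on the wild-type array and 38 were at least 2-fold higher. Of these, 24 and 2 genes reached 4-fold. Against the untreated iER71 array, a reference of another line added after the data were seen, 72 of the 140 were lower too and 8 of the 38 higher. The endothelial list held 12 of the 140, and the cardiac list 3 of the 38. Of the 12 genes with the largest differences, named next, each apart from Prkar2b lay below the detection level in Er71-deficient cells, so the size and order of these folds are uncertain. Higher in wild type were the matrix link protein gene Hapln1 (20.9-fold), the ETS factor Fli1 (20.3-fold), Cdh5 (19.2-fold), Tek (18.6-fold), Car8 (13.2-fold), the protein kinase A subunit Prkar2b (11.9-fold), the embryonic globin Hbb-y (10.8-fold), the adrenomedullin receptor partners Ramp2 (10.5-fold) and Calcrl (9.79-fold), the adhesion molecule Pecam1 (9.21-fold), the sialyltransferase St8sia1 (9.20-fold) and Tspan18 (7.79-fold). Higher in Er71-deficient cells were Myl7 (4.29-fold), Lhx1 (4.05-fold), Frzb (3.92-fold), the Wnt regulator Dact1 (3.15-fold), Cnn1 (3.06-fold), the histone gene H4c14 (2.91-fold), the meiotic gene Mnd1 (2.67-fold), Trim36 (2.58-fold), Mesp1 (2.57-fold), Stxbp6 (2.53-fold), Pdgfra (2.51-fold) and Rhpn2 (2.48-fold). H4c14 has near-identical copies in the genome, so its value is uncertain, and another St8sia1 probe set differed by only -0.38 on the log2 scale.

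In the endothelial list 12 of 31 genes were at least 2-fold lower without Er71 and none higher by that size, and the median difference (deficient minus wild type) was -0.66 against a random range of -0.11 to 0.00. Fli1, Cdh5, Tek and Pecam1 were the largest. In the blood list 8 of 22 genes were at least 2-fold lower without Er71, none was higher by that size, and the median was -0.57, below the random range. After Fli1 and Hbb-y came the homeobox gene Hhex (3.98-fold) and Kit (3.61-fold). Both lay below the detection level in Er71-deficient cells, so the size of their folds is uncertain. Hbb-y was dim on both iER71 arrays as well (log2 5.63 without and 4.94 with doxycycline, 5.29 in Er71-deficient cells and 8.71 in wild type), and Hba-x was also brightest in wild type. In the ETS family 5 of 14 genes were at least 2-fold lower, Fli1, Erg (6.18-fold), Elk3 (4.12-fold) and Ets2 (3.91-fold) among them. Erg, like Fli1, lay below the detection level in Er71-deficient cells, so its fold is uncertain. The list's median of -0.09 lay within the random range. With the stricter detection filter the median was -1.08, below the range of random lists of that filter. Genes of hypoxia and glycolysis had a median of -0.63, below the random range, with 3 of 12 past 2-fold: the oxygen-sensing hydroxylase Egln3 (2.69-fold), Bnip3 (2.18-fold) and the glucose transporter Slc2a1 (2.03-fold). The doxycycline array was lower than wild type for this list too, with a median of -0.22, below the random range. Slc2a1 was bright in wild type alone (log2 10.37, against 9.35 in deficient cells, 9.40 without and 9.56 with doxycycline). Bnip3 was dim in deficient cells alone (6.95, against 8.08, 8.08 and 8.10 in wild type, without and with doxycycline).

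Cardiac genes lay slightly higher in Er71-deficient cells, with a median of 0.23 above the random range of -0.12 to 0.01. Of 16, 3 passed 2-fold, namely Myl7, Mesp1 and Isl1 (2.21-fold), and none was lower by that size. Isl1 was dim in wild type alone (log2 6.49), at 7.63 in deficient cells and 7.55 without and 7.38 with doxycycline. Tnnt2 was 1.67-fold higher in wild type. Lhx1 and Mesp1 were the 2 of 15 primitive streak genes past 2-fold, and that list's median was 0.06, above the random range; Eomes was 1.49-fold and Mixl1 1.35-fold higher in deficient cells. The Wnt pathway list had a median of 0.00 (0.021 and above the random range with the stricter filter) and members on both sides: Frzb was higher in deficient cells, and Lgr5 (2.65-fold) and Rspo3 (2.25-fold) were higher in wild type. Pdgfra was the only one of 11 paraxial and lateral mesoderm genes past 2-fold (median 0.04, above the random range, and 0 with no detection filter, then within the random range). In the smooth muscle and pericyte list (median 0.23, above the random range, and 0.014 with no filter, then within the random range), Cnn1 was higher in deficient cells and Acta2 2.40-fold higher in wild type.

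The pluripotency median was 0.13, above the random range, with Nanog 2.31-fold and Pou5f1 1.72-fold higher in deficient cells. Both were dimmest in wild type. Pou5f1 was at log2 7.89 there, 8.68 in deficient cells, 8.68 without and 9.26 with doxycycline, and Nanog at 6.52, 7.73, 7.20 and 6.73. The list's median was also above the random range for the doxycycline array minus wild type, at 0.21. The neuroectoderm median was 0.02 with none of 12 past 2-fold. With the stricter filter it was 0.74 and above the random range, but rested on Fabp7 and Otx2 alone. Endoderm genes had a median of -0.05, with Hhex and Spink1 (2.24-fold) higher in wild type and Pdgfra higher in deficient cells. The immediate-early and stress list had a median of 0.14, above the random range of -0.14 to 0.01; Egr2 was 2.05-fold higher in deficient cells and Ier3 2.83-fold higher in wild type. The VEGF, FGF and MAPK median was -0.02 (-0.22 and below the random range with the stricter filter), with Flt1 2.33-fold higher in wild type. No gene passed 2-fold among those of fibroblast feeders (median 0.00), proliferation (-0.0032), the Notch pathway (-0.04), BMP and TGF-beta (0.00, and 0.042 and above the random range after cyclic loess) or ribosomal proteins (0.00). The percentiles of small medians such as 0.06 say little about size, because the random range is narrow. Slc2a1 was under 2-fold after cyclic loess, median centring or quantile normalization, and Bnip3, Egr2, Isl1, Nanog, Spink1, Stxbp6 and Slc2a1 were with an offset on the linear scale.

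**Figure D2:**
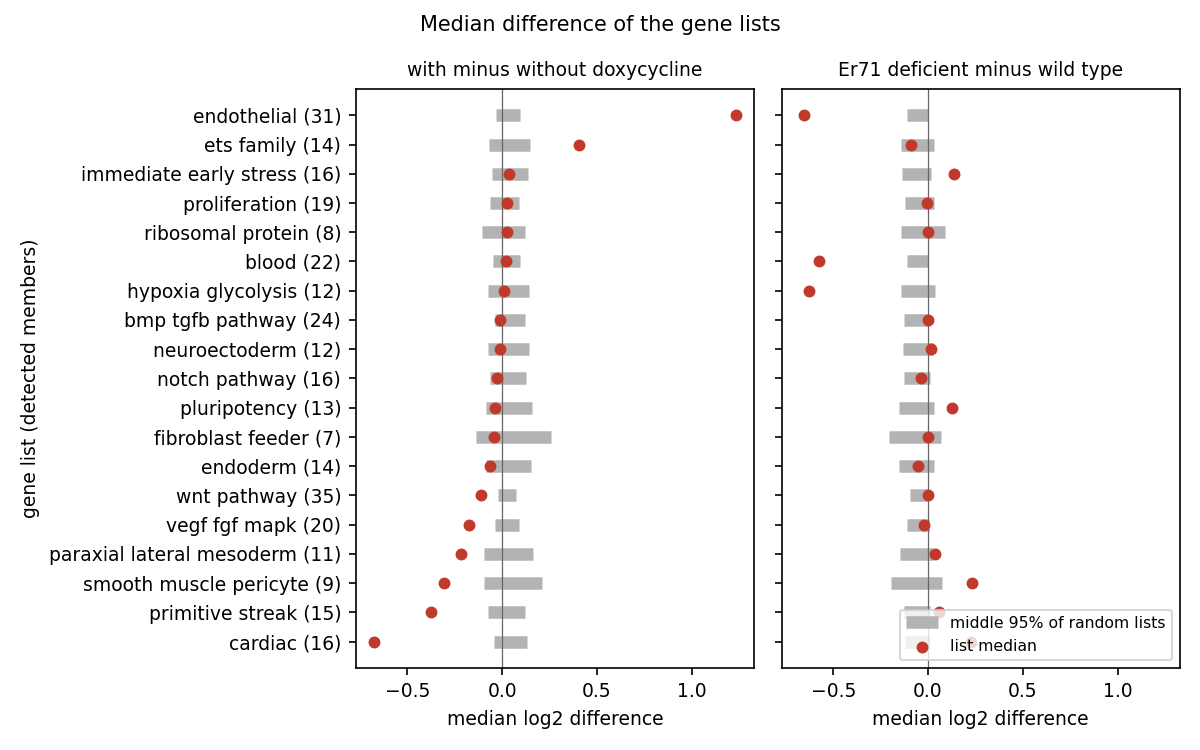
Median log2 difference (horizontal axis) of each of 19 gene lists, as points, with the middle 95% of 10000 random lists of matched expression as grey bars; the left panel is doxycycline (titled control) minus no doxycycline (titled ER71 overexpressed), the right panel Er71 deficient minus wild type. The endothelial median is 1.23 on the left and -0.66 on the right, and the cardiac median -0.68 and 0.23.

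The third comparison sets gain and loss side by side; these pairs share no array. By the titles, 69 genes past 2-fold in both pairs had the same direction (higher on the array titled ER71 overexpressed and on the Er71-deficient array, or lower on both) and 5 had opposite directions. With the sign turned to doxycycline minus untreated, 69 were opposite and 5 the same. Of the 140 genes lower in Er71-deficient cells, 55 (39.3%) were at least 2-fold higher with doxycycline (titled control), where independent lists would share 3.37. Tek, Cdh5 and the selenium transport gene Selenop (4.40-fold with doxycycline, 5.26-fold in wild type) were among those with the largest differences of this kind. Of the 38 genes higher in Er71-deficient cells, 14 (36.8%) were at least 2-fold higher without doxycycline, against 0.468 for independent lists, among them Lhx1, Frzb and Myl7. The 4 named genes lower both with doxycycline and in Er71-deficient cells were Rspo3, Lgr5, Spink1 and the guidance cue gene Sema3a (2.38-fold without doxycycline, 2.63-fold in wild type); the remaining gene, the olfactory receptor Olfr1155, lies outside the naming rule, was named after its values were seen, and was higher both with doxycycline and in Er71-deficient cells, by 1.66 and 1.69 on the log2 scale. Across the 8843 genes, which are not independent replicates, the differences correlated with Pearson's r of 0.41 and Spearman's rho of 0.26 by the titles, and -0.41 and -0.26 with the sign turned.

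**Figure D3:**
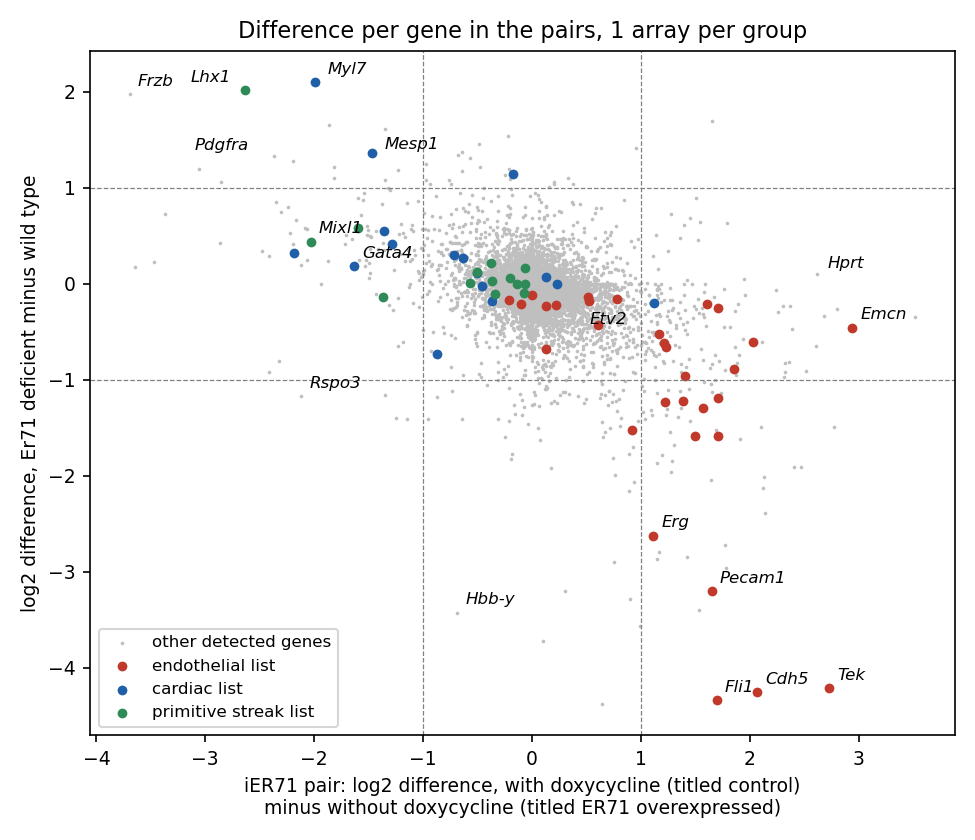
Log2 difference per detected gene in the iER71 pair, doxycycline (titled control) minus no doxycycline (titled ER71 overexpressed), on the horizontal axis, against Er71 deficient minus wild type on the vertical axis; dashed lines mark 2-fold, and a gene in several lists has the colour of the first. Endothelial genes such as Tek and Cdh5 lie at the lower right, and Lhx1, Myl7 and Frzb at the upper left.

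The reference arrays of the iER71 and Er71-deficient pairs, by their titles, also differed from each other. The doxycycline array (titled control) and the wild-type array differed by at least 2-fold in 363 genes, 233 of them higher with doxycycline and 130 higher in wild type, more than the 322 of the iER71 pair and the 178 of the Er71-deficient pair. Highest over wild type were Tmem255a, Dppa4, Lcp1, Emcn and Tlr3, with log2 differences of 3.52, 3.02, 2.93, 2.93 and 2.80. Highest in wild type over the doxycycline array were Rgs5, Hbb-y, Bmp5, the antioxidant enzyme gene Prdx2 and Vcan, by 4.30, 3.77, 3.70, 3.29 and 3.24. Tmem255a, Dppa4, Emcn and Tlr3 lay below the detection level in wild type, and Rgs5, Hbb-y and Bmp5 with doxycycline, so the size and order of these differences are uncertain. The endothelial list's median was 1.21 and the cardiac list's -0.94 (doxycycline array minus wild type). The iER71 array without doxycycline (titled ER71 overexpressed), chosen for this after the data were seen, differed from wild type in only 88 genes, 39 higher and 49 lower. The doxycycline and wild-type arrays differ in both line and treatment. Of their 233 and 130 genes, 171 and 71 were the same genes, in the same direction, as in the iER71 pair, where the line is shared. Both comparisons hold the doxycycline array, which by itself raises such overlap. With 1 array per group, neither line nor treatment can be told apart from array.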

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

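The test of exchanged titles was chosen only after the result was seen; those of globins, Hprt and normalization were written before their results were seen.

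Probe sets without a single gene name were left out of the report, and some differed between arrays. Among 3387 detected probe sets with no symbol, 265 differed by at least 2-fold in the Er71-deficient pair, 208 of them higher in deficient cells and 57 higher in wild type, the opposite balance to the named genes (38 and 140). The 208 were dim: their median log2 intensity was 6.77 in deficient cells, 5.29 in wild type, 5.99 without and 6.16 with doxycycline. In the iER71 pair 175 such probe sets differed, 139 higher with doxycycline (titled control) and 36 higher without. Among 402 detected probe sets with several symbols, 13 differed in the iER71 pair and 18 in the Er71-deficient pair, the latter led by the Hbb-bh1 and Hbb-bh2 probe set and by the Ctla2a and Ctla2b probe set (log2 4.47 in deficient cells, 9.80 in wild type).

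The first pattern weighed is that genes lower in Er71-deficient cells lay higher on the array titled control than on the array titled ER71 overexpressed. Of 140 such genes, 115 (82.1%) were higher on the array titled control, compared with 44.6% of all detected genes, and Etv2 was higher there too. After cyclic loess the share stayed at 82.1%. Loess evens out only shifts shared by genes of like intensity, and the values were already normalized. The result argues against a remaining shift of that kind and leaves other effects of normalization untested. Exchanged titles would give such a share too. The disagreement of the labels had raised this explanation before the values were seen, but its criterion was written after the share was seen. The share is therefore not an independent test of it and is not counted as support. With 1 array per state, exchanged titles and truly lower levels of these genes on ER71 overexpression both stay open, and no array was reassigned.

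The second pattern is that beta-like globin transcripts were above the detection level on the wild-type array alone, and Hba-x was brightest there while above that level on all 4 arrays. The Hbb-b1 and Hbb-b2 probe set was only just above it in wild type, at 6.21, and at most 2.91 elsewhere. The Hbb-bh1 and Hbb-bh2 probe set had a log2 intensity of 9.21 in wild type and at most 4.50 elsewhere, Hbb-y 8.71 and at most 5.63, and Hba-x 7.61 and at most 6.90. Erythroid cells among the sorted wild-type cells are a candidate source, although the Flk-1 gate would remove mature ones. Over 8 detected of 24 erythroid genes other than globins, the median excess of wild type over the highest other array lay at the 98.8th percentile of matched random lists, as that source would need; it was 0.05 on the log2 scale, 4 of the 8 were above 0 and none reached 2-fold. Car2 and Tfrc, bright on every array, differed by -0.14 and 0.14, and below the detection level Alas2, Epb42 and Klf1 differed by 0.29, 0.29 and 0.13 and Slc4a1 by 0, so such cells stay open, as does a difference between the lines, which was not tested.

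The third pattern concerns Hprt, whose log2 intensity was 6.81 without doxycycline and 9.43 with it in the iER71 line, against 10.64 in Er71-deficient cells and 10.55 in wild type. After cyclic loess the difference with doxycycline was 2.60. Loess evens out shifts shared by many genes and would hardly change a single gene, so normalization stays undecided here. For lower copy number of the region in the iER71 line, the criterion written beforehand asked for a clearly negative median. It was taken over the 6 nearest detected genes in the gene order of assembly GRCm38.p6. The brighter iER71 array minus the dimmer other array had a median of 0.022, so the criterion was not met. This measure takes the brighter iER71 array and the dimmer other array, so it leans away from negative values. It therefore cannot decide on loss of the whole region. Plac1 and Fam122b were at -1.14 and -1.05, while Phf6 was at 0.57 and Mospd1 at -0.10. A630012P03Rik and Gpc3 were at 0.36 and 0.14. Both were dim with doxycycline, at log2 5.76 and 8.54, against at least 8.25 and 10.81 on the other arrays. Loss of a part stays open too. Some doxycycline-inducible ES lines carry their construct beside Hprt, and such a placement here may be worth checking; it was not tested.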

How the results depend on the processing

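Choices were fixed before the data were examined, except 4 that are named as added. No array could be left out, because each group has 1. No paired analysis was possible because each group has 1 array. Under cyclic loess, median centring, quantile normalization and the mean of probe sets, every count of genes past 2-fold in the 3 pairs stayed within 1.5 times its value and the correlation kept its sign; median centring moved the median of all genes by at most 0.08. An offset of 32 left 137 genes higher with doxycycline (titled control) and 72 higher without, 78 lower and 17 higher in Er71-deficient cells, 140 higher with doxycycline than in wild type, and 2 opposite and 43 same by the titles; the cause is its shrinking of dim genes. At 1.5-fold the counts were 558 and 280, 394 and 136, 539 and 391 (control pair), 28 opposite and 238 same; at 3-fold they were 65 and 40, 44 and 6, 67 and 53, 1 and 18. Genes higher in Er71-deficient cells numbered 78 with no detection filter and 23 with the stricter one, and 9 genes were opposite with no filter. Turning the sign gave 69 opposite, 5 same and a correlation of -0.41, and left the counts per array as they were. Of 266 list medians compared, 254 kept their side of the random range, and those outside it kept their direction too. A change of sign within the range was not counted. With no filter, in Er71-deficient cells, paraxial and lateral mesoderm became 0, smooth muscle and pericytes 0.014 (both now within the random range) and neuroectoderm 0.012 (now outside). With the stricter filter, the iER71 medians became -0.76 for pluripotency and -0.99 for neuroectoderm (both now outside) and -0.0034 for VEGF, FGF and MAPK (now within). The Er71-deficient medians became 0.021 (Wnt pathway), 0.74 (neuroectoderm), -0.22 (VEGF, FGF and MAPK) and -1.08 (ETS family), all now outside. In both pairs the neuroectoderm median under that filter rested on Fabp7 and Otx2 alone. BMP and TGF-beta in that pair was 0.042 with loess and 0.0021 with the offset, both outside. The cause was not tested, and fewer genes remain under the stricter filter. Among the named genes past 2-fold none reversed, while a change of sign under 2-fold was not counted. Of 1420 values compared, 18 fell under 2-fold and 2 passed it. Of the added alternatives, leaving out genes with equal values on 2 arrays moved no count by over 1.5 times. With wild type as the reference, 233 genes were higher and 130 lower with doxycycline; this and the iER71 pair share the doxycycline array. With the untreated iER71 array as reference, 105 genes were lower and 43 higher in Er71-deficient cells, and 72 and 8 were the same genes as against wild type; sharing the Er71-deficient array by itself raises such overlap, and no value without effect was computed. The untreated iER71 array in the control pair gave 39 and 49. The number of arrays limits precision throughout.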

Other observations

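The comparisons in this part were chosen only after the result was seen. The array with doxycycline (titled control) stood furthest from the rest. There, 169 genes were at least 2-fold higher than on all of the other 3 arrays and 69 at least 2-fold lower than on all of them, 238 in sum, against 75 for the Er71-deficient array (6 higher, 69 lower), 11 for wild type and 10 for the array titled ER71 overexpressed. Of the 169, 58 were below the detection level on the other arrays, Emcn and Edn1 among them. The endothelial list gave 17 of the 169, and 10 of the 69 genes at least 2-fold lower in Er71-deficient cells than on all other arrays.

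The germ-cell RNA helicase gene Ddx4 and the synaptonemal complex gene Sycp3, picked after their values were seen, were 2.84-fold and 3.46-fold higher with doxycycline than without, at log2 intensities of 7.22 and 7.47, while Dazl, below the detection level on every array, differed by 1.03-fold. Both iER71 arrays differed from both other arrays by at least 2-fold in 19 genes. Lower in the iER71 line were the peroxiredoxin gene Prdx2 (log2 8.85 and 7.99 against 11.10 and 11.28), Scoc, Spin2c, Car4, H2bc22, Plac1, Pcsk5, Nexn, Hprt, Magel2, Fam122b and Hand1. Higher were Adam23 (9.13 and 8.99 against 7.08 and 7.63), Exoc3l, the DNA sensor Aim2, Prom1, Slc7a7, the epithelial cadherin Cdh1 and H2bu2. The other pairings of the 4 arrays gave 5 and 2 such genes.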
